A study of Arabidopsis thaliana with 23 samples.

How the data were processed

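RNA abundance was measured on Affymetrix ATH1 arrays in root cells of Arabidopsis seedlings grown for 5 days. The sources used here disagree on the tissue: the series description and the source names give fluorescence-sorted cells, while the protocol text of all 23 samples describes cut roots taken into RNA buffer. The texts follow the former; if the time-course RNA came from whole roots, the ground tissue values and the CEI comparisons would mean something else. The deposited values are signal intensities on a linear scale that the authors made with MAS5, scaled per array. The mean of the values between the 2nd and 98th percentile lay between 249.88 and 249.90 on all 23 arrays, and no log transformation or quantile normalization was found in the values. The version of MAS5, detection calls and filters are not given in the sources used here. Per the labels, the time-course arrays have 2 biological replicates per time point and the CEI group has 3, with RNA amplified in 2 cycles before hybridization. No time course on medium without Dex is among the samples, so time on Dex and time after the transfer vary together.

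The table held 22810 probe sets, of which 64 controls were kept apart. A pseudocount of 10, the 20th percentile of all values, was added and log2 taken, with no further normalization. A probe set was tested when its value was above the 40th percentile of its own array on at least 2 arrays, which left 15983. The largest difference between group means of the median shift over all probe sets was 0.17 on the log2 scale. The number of arrays limits the precision of each value. The median standard error was 0.38 (log2) for a time point against 0 h, 0.29 for CEI cells against the 4 ground tissue arrays of a time, and 0.17 for the mean difference between the lines.

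A single limma fit (version 3.58.1, R 4.3.3, lmFit and eBayes with trend) took the 11 group means of all 23 arrays, with 12 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the 15983 probe sets at a threshold of 0.05. All tests were two-sided. The comparisons were each time point against 0 h within a line, a moderated F-test over the time course of each line, the difference between the lines in these changes, the mean difference between the lines over the 5 time points, and CEI cells against the mean of both lines at 0 h and at 12 h. The p-values measure spread between biological replicates as the labels define them. For the mean difference between the lines all arrays of a line count as independent, though replicate differences correlated across times (median 0.39 in the SHR line and 0.24 in the SCR line). If arrays with the same replicate number belong together, its standard errors and p-values are too small. The same fit was tested on simulated data made from these arrays, with 200 probe sets changed. Its noise was drawn independently for each probe set and array, without shared runs or outlying arrays. The recovery given next may therefore be too high for the real arrays. A log2 change of 2 was recovered for 79.4% of changed probe sets in the SHR line at 12 h, 70.2% in the SCR line at 12 h, 100% between the lines and 93.1% in CEI cells at 0 h, and a log2 change of 1 for 15.2%, 10%, 86.6% and 21.9%.

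Gene names came from the annotation supplied for the probe sets. It gave 1 gene for 13513 probe sets and several for 503, and did not list 8730. Of the tested probe sets 8850 (55.4%) named 1 gene, and of the 182 loci on the gene lists 28 were named and 27 tested. SHR, SCR, CYCD6;1, MGP and NUC were not named by it, so the labels were not checked through the induced genes. A probe set marked _s_at can bind transcripts of several genes.

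The comparisons, the threshold, the rule for named genes, the alternatives and 17 gene lists were fixed before the data were examined. The lists were SHR/SCR pathway, endodermis barrier, cortex markers, G2/M cell cycle, DNA replication, G1 regulators, morning-phased clock, evening-phased clock, touch, wound and stress, heat shock, gibberellin, cytokinin response, auxin response, stele markers, epidermis markers, root cap markers and stem cell niche. G1 regulators, morning-phased clock, heat shock, stele markers and root cap markers had 0 tested members. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, in 45 tests over 15 contrasts. A further 37 families of gene symbols with at least 5 members, and the plastid genome among them, were defined after the annotation was seen and tested the same way in 555 tests. With a correlation estimated from the data, 0 of the 13 list calls and 0 of the 43 family calls passed 0.05, and the lowest adjusted p was 0.391 for lists and 0.820 for families. With fry, which tests whether a set's genes move on balance one way, 13 family tests passed.

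The rule for named genes took every tested member of the SHR/SCR pathway list. From each other list it took up to 4 members with the smallest adjusted p past the threshold. It also took the 6 largest rises and the 6 largest falls among probe sets past the threshold that name 1 gene and whose groups do not overlap (for a time course, at 12 h, with the 3 largest rises and falls at 1 h). Ranks were by log2 change. Other genes are named as chosen after their values were seen.

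Alternatives were a pseudocount of 1 or 40, no filter, quantile normalization, eBayes without trend, a fit of only the arrays of the contrast, replicate number as a block, and leaving out each array in turn. Added after seeing the data were the 3' to 5' signal ratio of 3 control genes as a covariate, a single line as the control of the CEI cells, and the line difference without the 12 h arrays. For the 3 lists, another pseudocount, a single control line and leaving out arrays were added after seeing the data. For families, all alternatives were added then.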

Results

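The arrays measured transcript levels in root ground tissue, the cortex and endodermis layers, sorted by the J0571 enhancer-trap marker according to the series description; the sample protocol describes cut roots instead. A pair of transgenic lines carried inducible versions of SHORT-ROOT (SHR) or SCARECROW (SCR), GRAS transcription factors that pattern the ground tissue. Both lines were moved to 1 micromolar Dex, which switches on the inducible protein, and sampled at 0, 1, 3, 6 and 12 h with 2 arrays each, 20 in all. A further 3 arrays came from cortex/endodermis initial (CEI) cells, the stem cells whose daughter divides asymmetrically into cortex and endodermis, sorted with a CYCD6 promoter GFP marker on standard medium. Median signal per array ran from 62.9 to 79.8 and the highest signal from 11625 to 18360. Correlation across genes between replicate arrays was 0.862 in the SCR line at 6 h and at least 0.914 in every other group; genes are not independent replicates.

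On the component with the most variance (42.2%) the arrays followed a common early course and then parted by line. Both lines had low scores on it at 1 h, −61.3 and −46.9 in the SHR line and −59.9 and −26.4 in the SCR line. By 12 h the SHR line stood at 52.2 and 51.1, towards the CEI cells at 83.9 to 89.9, and the SCR line at −40.1 and −45.5. The SCR arrays at 6 h lay apart from each other at −88.2 and 6.99. The second component (11.9%) separated the lines at every time, 0 h included. Scores on it were 14.9 to 37.5 in the SHR line and −34.6 to −13.3 in the SCR line. The CEI arrays, at −31.6 to −19.5, lay within the SCR range there.

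**Figure D1:**
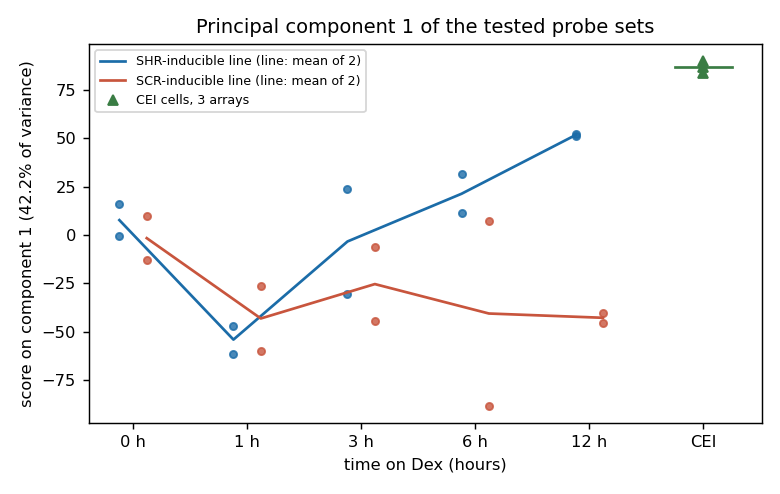
Score of each array on principal component 1 (no unit) against time on Dex in hours, with CEI cells at the right; points and triangles are single arrays and lines are means. On this component SHR-line arrays at 12 h (52.2 and 51.1) sit nearest the CEI arrays.

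Which genes respond to SHR over time was asked in the SHR-inducible line. AT1G05370 rose most clearly, from a signal of 6.18 ± 6.14 (SD, n = 2) at 0 h to 107 ± 11.8 at 3 h and 259 ± 140 at 6 h. Its log2 change at 6 h was 4.00 ± 0.55 (SE, adjusted p = 0.0110), with both 6 h arrays above both 0 h arrays. The probe set 255422_at, which has no gene in the annotation used here and was chosen after its values were seen, rose by 2.89 ± 0.40 at 6 h (adjusted p = 0.0110). These were the 2 probe sets past the threshold at 6 h. With 267496_at, chosen in the same way, which stood at 253 ± 1.94 at 0 h, 1061 ± 19.8 at 1 h and 129 ± 81.6 at 12 h, they were the 3 that changed over the whole course (F-test, adjusted p = 0.0166, 0.0478 and 0.0478).

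Of the 12 members of the SHR/SCR pathway list 3 were tested. SLY2 (AT5G48170, also called SNEEZY), an F-box protein of gibberellin signalling, had signals of 66.0 ± 38.6 at 0 h, 265 ± 8.64 at 3 h, 528 ± 114 at 6 h and 287 ± 82.5 at 12 h (SD, n = 2). Its log2 difference from 0 h was 2.91 ± 0.61 at 6 h and missed the threshold (adjusted p = 0.267). AT5G41920 (SCL23), a GRAS relative of SCR, differed from 0 h by 0.78 ± 0.33 at 6 h, and JKD, a zinc-finger protein that binds SHR and SCR, by 0.77 ± 0.46 at 12 h. As a group the list rose at 3 h (median 0.30, adjusted p = 0.0367), 6 h (median 0.78, adjusted p = 0.00299) and 12 h (median 0.77, adjusted p = 0.0365). The calls were lost with an estimated correlation (adjusted p = 0.406, 0.391 and 0.406 with an estimated correlation). They also ended without SHR 0 h replicate 2 (medians 0.28, 0.77 and 0.49), the 3 h call without SHR 3 h replicate 2 (0.25) and the 12 h call without SHR 12 h replicate 1 (0.39). Of its members 0 were called at 6 h over all probe sets and 2 adjusted over the list alone.

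**Figure D2:**
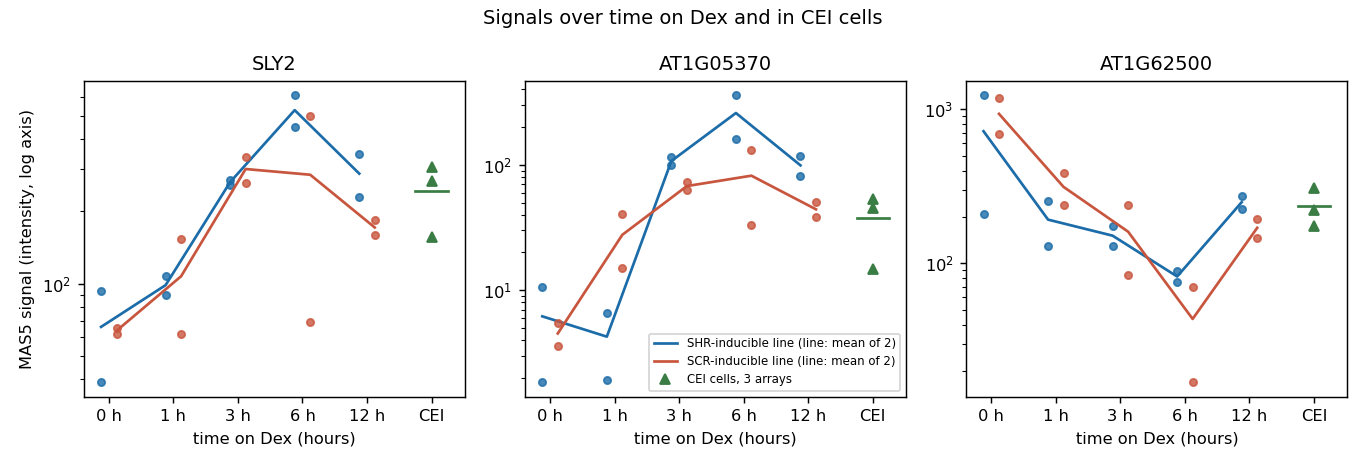
MAS5 signal (intensity, log axis) of SLY2, AT1G05370 and AT1G62500 against time on Dex in hours; circles are single arrays of each line, lines join the means of 2 arrays, and triangles with a bar are the 3 CEI arrays and their mean. AT1G05370 reached 259 at 6 h in the SHR line, and AT1G62500 was lowest at 6 h in both lines.

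The gibberellin list, with the receptors GID1A, GID1B and GID1C, had a median log2 change of 0.91 at 1 h (adjusted p = 0.0115), 0.68 at 3 h (adjusted p = 0.0115) and 0.65 at 6 h (adjusted p = 0.0490), and these calls were lost too (adjusted p = 0.406, 0.406 and 0.435 with an estimated correlation). They ended without SHR 0 h replicate 2 as well (0.62, 0.38 and 0.26), without SHR 1 h replicate 1 (0.46) or SHR 3 h replicate 1 (0.65) at those times, and without either SHR 6 h array (0.45 and 0.68). The auxin list, with the conjugating enzymes GH3.3 and WES1 and the lateral root regulators LBD16 and LBD29, rose at 1 h by a median of 1.00 (adjusted p = 0.0397, and adjusted p = 0.492 with an estimated correlation), a call that ended without SHR 1 h replicate 1 (0.55) or SHR 0 h replicate 2 (0.40). At 1 h, 1 member of each list passed when adjusted over the list alone, and 0 over all probe sets. Among genes chosen after their values were seen, the multicopper oxidase LPR1 differed by 2.08 at 6 h (adjusted p = 0.107), SOL1 by 2.81 (adjusted p = 0.107), and at 12 h AT5G45210 by 4.51 and the peroxidase AT4G11290 by 3.22 (adjusted p = 0.0629 each).

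In limma the single time points called 0 probe sets at 1 h, 0 at 3 h, 2 at 6 h and 0 at 12 h, beside 2549, 439, 508 and 1406 at unadjusted p under 0.05, and the F-test called 3 beside 2756. The F-test count was 147 without SHR 3 h replicate 2, 78 without SHR 3 h replicate 1, 1 without SHR 0 h replicate 1, SHR 6 h replicate 2 or SHR 12 h replicate 2, and 0 without SHR 6 h replicate 1 or SHR 1 h replicate 2. At 6 h the count was 0 without SHR 6 h replicate 1, SHR 6 h replicate 2 or SHR 0 h replicate 2 and with only the arrays of the contrast. At 3 h it was 1 without SHR 3 h replicate 1 or SHR 0 h replicate 2, and at 12 h it was 1 without either SHR 0 h array. The AT1G05370 value was 3.45 without SHR 6 h replicate 1, 3.61 without SHR 0 h replicate 2 and 4.56 without SHR 6 h replicate 2, each without a call. The 6 h call of 255422_at also ended without SHR 0 h replicate 1 (2.87, adjusted p = 0.115). Replicate differences in this line correlated across times (median 0.39), which the main fit leaves out. With replicate number as a block the counts were 332, 1, 20 and 6 at 1, 3, 6 and 12 h and 1254 in the F-test, and SLY2 passed at 6 h (adjusted p = 0.0241).

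Which genes respond to SCR was asked in the same way. The probe set 259008_at, chosen after its values were seen and without a gene in the annotation used here, rose from 145 ± 6.11 (SD, n = 2) at 0 h to 726 ± 211 at 12 h, a log2 change of 2.22 ± 0.28 (SE, adjusted p = 0.00521), with both 12 h arrays above both 0 h arrays. In the SHR line it differed from 0 h by 0.76, 0.84 and 0.98 at 1, 3 and 6 h, without a call. The difference between the lines at 12 h (−1.21) did not pass either, so this rise is not shown to be particular to the SCR line. AT1G62500, known as CO2, a marker of the cortex, had signals of 933 ± 344 at 0 h and 43.5 ± 37.7 at 6 h, and just missed the threshold (log2 difference −4.30, adjusted p = 0.0503, chosen after its values were seen). The glutathione transferase ATGSTF13, chosen likewise, differed by −2.90 at 6 h (adjusted p = 0.0503) and AT4G15975 by 3.20 at 1 h (adjusted p = 0.0532). In the SHR line AT1G62500 differed by −2.51 at 6 h, with 0 h arrays that spread widely (720 ± 721).

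The SHR/SCR pathway list was called higher at 3 h in this line as well, by a median of 0.49 (adjusted p = 0.0405, and adjusted p = 0.424 with an estimated correlation). Adjusted over the list alone, 1 of 3 members passed. SLY2 differed by 2.07, JKD by 0.49 and AT5G41920 by −0.14, so not every member rose. The call ended without SCR 0 h replicate 1 (0.24) or SCR 3 h replicate 1 (0.22). SLY2 had signals of 63.6 ± 2.54 at 0 h, 300.2 ± 53.3 at 3 h and 171 ± 16.9 at 12 h (SD, n = 2), and log2 differences of 2.07 at 3 h and 1.45 at 6 h that did not pass. AT1G05370 stood at 4.51 ± 1.28 at 0 h and 67.7 ± 7.34 at 3 h, a log2 difference of 2.42 that did not pass. The division genes AUR1 and AUR2 (Aurora kinases) differed at 1 h by −1.24 and −1.53 and the replication genes ICU2 (DNA polymerase alpha) and PRL (MCM7) by −0.82 and −1.07. Both tested members of each list passed when adjusted over the list alone and 0 over all probe sets. The stress genes WRKY53 and STZ, at 1 h, passed in the same way, upwards, and again 0 passed over all probe sets. Over the 8 time contrasts of both lines, 0 members of the 12 lists with a tested member were called over all probe sets.

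In limma the SCR line gave 0 probe sets at 1 h, 0 at 3 h, 0 at 6 h and 1 at 12 h, beside 1181, 290, 840 and 1236 at unadjusted p under 0.05, and the F-test gave 0 beside 547. Single arrays decided several of these counts. The SCR 6 h arrays had mean correlations with the other arrays of 0.847 (replicate 1) and 0.930 (replicate 2). A count without either of them rests on the other alone. Without SCR 6 h replicate 2 the 6 h count was 1960 and the F-test count 526, without SCR 6 h replicate 1 they were 3 and 17. Without SCR 1 h replicate 1 the 1 h count was 90 and the F-test count 30, and the 12 h count was 3 without SCR 12 h replicate 1 and 0 without SCR 12 h replicate 2 or either SCR 0 h array. The value of 259008_at was then 1.93, 2.26 or 2.18. With replicate number as a block the counts were 3, 4 and 4 at 1, 6 and 12 h and 4 in the F-test. With only the arrays of the contrast the 12 h count was far larger, as given below with the processing.

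Whether the lines responded alike was asked from the differences between their changes. Gene groups parted by 12 h. The autophagy genes (ATG, 8 probe sets, mostly ATG8) fell in the SHR line by a median of 0.69 (adjusted p = 0.0114) and rose in the SCR line by 0.52 (adjusted p = 0.00270), and the changes differed (median −1.13, adjusted p = 0.000265). The calmodulin-like calcium sensors (CML, 7 probe sets) fell in the SHR line (median −0.78, adjusted p = 0.0390) and rose in the SCR line (median 0.55, adjusted p = 0.0178), with a difference of −1.75 (adjusted p = 0.00298). The tau-class glutathione transferases (GSTU, 8 probe sets) rose in the SCR line at 12 h (median 0.72, adjusted p = 0.00806), and the lines differed by −1.20 (adjusted p = 0.0132). The 68 probe sets of the plastid genome rose in the SHR line at 1 h by a median of 0.59 (adjusted p = 2.57e-08) against 0.02 in the SCR line, with a difference of 0.56 (adjusted p = 2.24e-06). Each of these family calls was lost with an estimated correlation (adjusted p of 0.820 or more). In the SHR line the ATG call ended without SHR 0 h replicate 1 (−0.34), the CML call without any of the 4 arrays (−0.56 to −0.80) and the plastid call without SHR 0 h replicate 2 (0.19). The GSTU difference ended without SHR 0 h replicate 2 (−1.05), and the plastid difference ended without that array (0.19) and turned without SCR 1 h replicate 2 (−0.06).

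**Figure D3:**
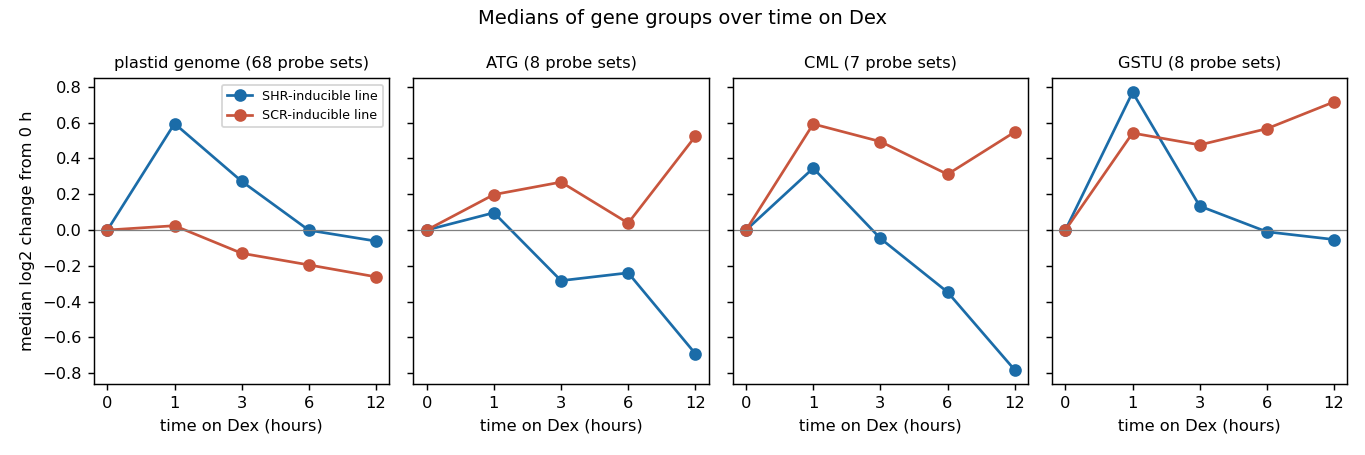
Median log2 change from 0 h of the plastid genome, autophagy (ATG), calmodulin-like (CML) and glutathione transferase (GSTU) groups against time on Dex in hours, for each line. At 12 h the ATG and CML medians lie below 0 in the SHR line (−0.69 and −0.78) and above 0 in the SCR line (0.52 and 0.55).

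No single gene passed for this difference. AT5G45210 and AT1G05370 had the same direction in both lines at 6 and 12 h, and SLY2 at every time point. Across genes, which are not independent replicates, the changes of the lines had r = 0.47 at 1 h, 0.20 at 3 h, −0.04 at 6 h and −0.19 at 12 h. At unadjusted p under 0.05, 123 probe sets were higher in both lines at 1 h where 39.8 would be expected and 175 lower in both where 55.0 would be, with 10 opposite (93.6 expected). At 3 h 31 were higher in both (2.66 expected), 10 lower in both (1.42) and 1 opposite (3.89), and at 6 h 32 (3.44), 15 (7.61) and 6 (15.7). At 12 h the numbers were 33 (33.8), 18 (20.9) and 96 (54.0). No probe set was called in both lines at 12 h, so the planned exact test of shared calls had nothing to compare.

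In limma the differences between the lines gave 0 probe sets at 1, 3, 6 and 12 h and 0 in the F-test, beside 564, 211, 632, 1944 and 1170 at unadjusted p under 0.05. Counts without an SCR 6 h array again rest on the other SCR 6 h array alone. Without SCR 6 h replicate 2 the 6 h count was 1321 and the F-test count 1214, without SCR 1 h replicate 1 the 1 h and F-test counts were 3, without either SHR 3 h array the F-test count was 29, and without SHR 0 h replicate 2 the 3 h and 12 h counts were 1. With replicate number as a block the F-test count was 91. The 12 h correlation ran from −0.28 without SHR 0 h replicate 2 to −0.040 without SHR 0 h replicate 1, with −0.25 without SHR 12 h replicate 1 or SCR 0 h replicate 1, −0.09 without SHR 12 h replicate 2 and −0.08 without SCR 0 h replicate 2.

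The difference between the lines was also averaged over the 5 time points. The F-test of a change of this difference over time called 0 probe sets (lowest adjusted p = 0.166). Transcripts of the plastid genome were higher in the SHR line, by a median log2 of 0.99 over 68 probe sets (adjusted p = 7.81e-19, and adjusted p = 0.820 with an estimated correlation), with 48 called higher. The median was already 0.74 at 0 h, and 1.25, 1.17, 0.93 and 0.85 at 1, 3, 6 and 12 h. Its member atpH, a subunit of the plastid ATP synthase, had signals of 933 ± 315 in the SHR line and 307 ± 92.5 in the SCR line (SD, n = 10), a difference of 1.55 ± 0.19 (SE, adjusted p = 4.71e-05). AT1G19210, an AP2/ERF transcription factor, was higher by 1.89, AT4G29020 by 2.07, AT5G60350 by 1.60, AT2G07776 by 1.56 and AT2G07695 by 1.51. AT5G01380, a trihelix transcription factor, was lower, at 143 ± 143 against 1115 ± 899, a difference of −3.13 ± 0.30 (adjusted p = 4.7e-06). MSRB6, a methionine sulfoxide reductase, was at −2.64, AT3G19920 at −2.30, AT1G50290 at −2.16, AT5G24240 at −2.02 and AT1G76210 at −1.96.

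Among the lists, the auxin list was lower in the SHR line (median −0.88, adjusted p = 0.0365, and adjusted p = 0.492 with an estimated correlation), with GH3.3 at −1.90 and LBD16 at −1.56 called, 2 members over all probe sets and 2 adjusted over the list alone. The list call ended without SHR 1 h replicate 1 (−0.94), SHR 0 h replicate 2 (−0.80) or SCR 1 h replicate 1 (−0.83). GID1B, a gibberellin receptor, was lower, at −1.04 (1 of 3 in either count). Both tested endodermis barrier genes were lower, the receptor kinase GSO1 at −0.85 (adjusted p = 0.0140) and AT1G61590 at −1.17 (adjusted p = 0.0125), also adjusted over the list alone. AT5G41920 was higher by 0.43 (adjusted p = 0.0450) and WRKY53 by 0.89 (adjusted p = 0.0368). The ATG group was lower, with a median of −0.56 (adjusted p = 0.000487), with ATG8E at −2.02 and ATG8H at −1.87 among 5 called (adjusted p = 0.820 with an estimated correlation).

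In all, 1965 probe sets were higher in the SHR line and 1643 lower, 674 of them by more than 2-fold. The arrays of a line came from 2 biological replicates per time point and were counted as independent across times, so these calls may be too many. At single times, added after seeing the data, 1 probe set differed at 0 h, 22 at 1 h, 23 at 3 h, 52 at 6 h and 2117 at 12 h, and 1443 for the mean without the 12 h arrays. Such counts do not test a change between times. Every SHR-line array, and no other, carried the spiked control transcript dap at a signal above 112, so this control and the line coincide.

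**Figure D4:**
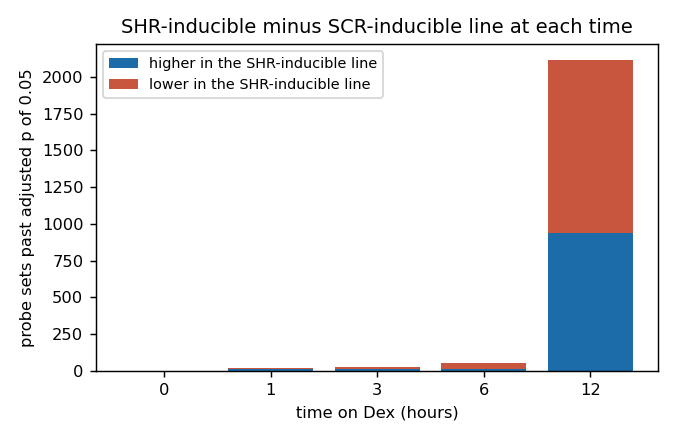
Number of probe sets that differ between the lines past the threshold at each time on Dex in hours, stacked as higher (blue) and lower (red) in the SHR-inducible line. The count is 2117 at 12 h and at most 52 earlier, and such counts do not test a change between times.

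CEI cells were set against ground tissue at 0 h to ask what marks the initial cell. XTH21, a cell-wall xyloglucan enzyme, had a signal of 451 ± 121 (SD, n = 3) in CEI cells against 14.4 ± 9.76 (n = 4), a log2 difference of 4.30 ± 0.48 (SE, adjusted p = 2.99e-05). BBM, an AP2 transcription factor of the root meristem, was higher at 456 ± 115 against 86.0 ± 26.4, a difference of 2.30 ± 0.47 (adjusted p = 0.00277). The Aurora kinases of cell division were both higher, AUR1 by 1.14 (adjusted p = 0.0291) and AUR2 by 1.38 (adjusted p = 0.0329). SLY2 was higher by 1.76 ± 0.46 (adjusted p = 0.0137). AT5G45210 was higher by 4.37, AT4G11290 by 4.30, AT3G50190 by 3.42, AT5G62330 by 3.17 and AT3G53650 by 3.09.

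AT2G38870 had a signal of 13.7 ± 5.53 (SD, n = 3) in CEI cells against 1579 ± 772 (n = 4), a log2 difference of −5.90 ± 0.48 (SE, adjusted p = 1.71e-06). AT2G19970 was lower at −5.61, the peroxidase AT5G64120 at −4.96, the auxin-conjugating enzyme GH3.3 at −4.75, AT3G10950 at −4.36 and AT4G15390 at −4.17. Both tested genes of the touch, wound and stress list were lower, the zinc-finger protein STZ at −2.66 (adjusted p = 0.000107) and WRKY53 at −1.84 (adjusted p = 0.0158). The WRKY transcription factors as a family were lower (5 probe sets, median −1.82, adjusted p = 0.0281, 4 called), and so were the calmodulin-like genes (7 probe sets, median −1.12, adjusted p = 0.0156, 4 called, with CML37 at −3.60). With an estimated correlation both calls were lost (adjusted p = 0.820 with an estimated correlation). GI, an evening clock gene, was lower, at −1.43 (adjusted p = 0.000196).

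The cortex markers AT1G62500 (CO2) and AT1G09750 (PEP) were lower in CEI cells, at −1.53 (adjusted p = 0.0399) and −1.83 (adjusted p = 0.0426). The epidermis markers EXPA7 and EXPA18 differed by 0.60 and 1.05 and did not pass. The auxin list was lower (median −0.97, adjusted p = 0.0409, and adjusted p = 0.492 with an estimated correlation), with 1 member called over all probe sets and 2 adjusted over the list alone. The list call ended without SHR 0 h replicate 1 (−0.76) or 2 (−1.18), SCR 0 h replicate 2 (−0.78), or CEI replicate 2 (−1.07) or 3 (−0.53). Replication genes ICU2 (0.63) and PRL (0.77) passed only adjusted over the list alone (2 of 2, and 0 over all probe sets), as did AGL42 of the stem cell niche list (0.97) beside BBM. Adjusted over the list alone, 2 of 2 cortex, 2 of 2 division, 2 of 2 stress and 1 of 3 pathway genes passed, as they did over all probe sets. The cytokinin response genes ARR15 and RR16 differed by −0.88 and −0.68 and did not pass. Plastid genome transcripts were lower in CEI cells, with a median of −0.97 (adjusted p = 5.35e-14, and adjusted p = 0.820 with an estimated correlation). It was −0.64 against the SCR line alone and −1.27 against the SHR line alone, which carries the spiked control.

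**Figure D5:**
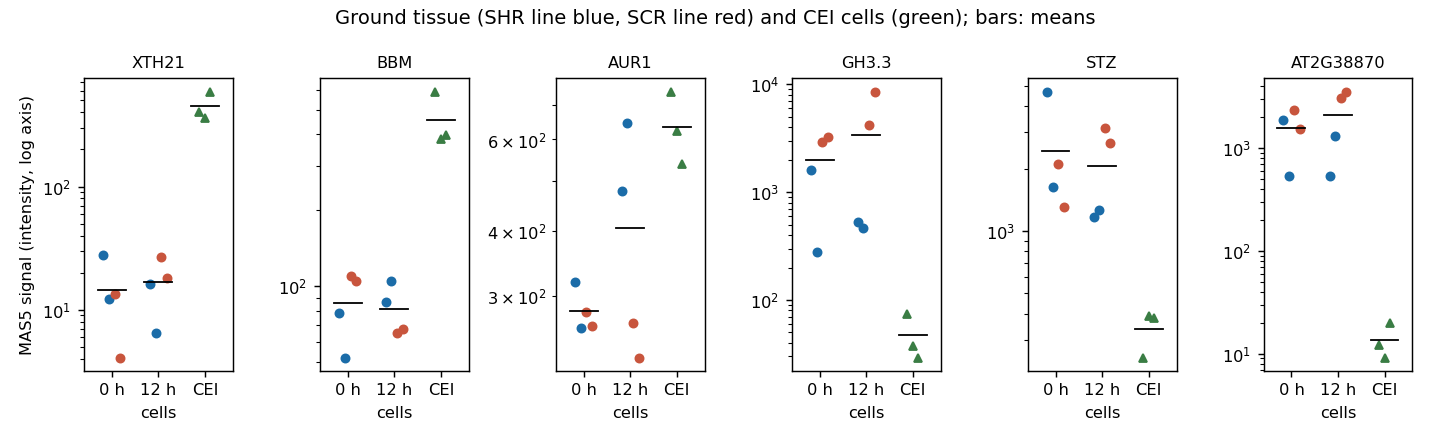
MAS5 signal (intensity, log axis) of 6 genes in ground tissue at 0 h and 12 h on Dex (circles, SHR line blue and SCR line red, 2 arrays each) and in CEI cells (green triangles, 3 arrays); bars are means. XTH21 and BBM are higher in CEI cells at 451 and 456, and AT2G38870 is lower at 13.7.

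CEI cells differed from ground tissue at 0 h in 3241 probe sets, 1538 higher and 1703 lower, 2142 of them by more than 2-fold. The count was 1766 without SCR 0 h replicate 1, 2054 without CEI replicate 1, 2065 without CEI replicate 2, and against 1 line alone (added after seeing the data) 1827 with the SCR line and 2123 with the SHR line. Some calls ended without 1 array. The Aurora kinases did, AUR2 (any of the 7, 1.27 to 1.45) and AUR1 (SHR 0 h replicate 2, either SCR 0 h array, CEI replicate 1 or 2, 1.02 to 1.16). The cortex pair did too, AT1G62500 (all but SHR 0 h replicate 2, −0.90 to −1.73) and AT1G09750 (SHR 0 h replicate 1 −1.39, SCR 0 h replicates −1.87 and −1.79, CEI replicate 1 −0.85). The others were WRKY53 (SHR 0 h replicate 1 −1.59, SCR 0 h replicate 1 −1.51, CEI replicate 2 −1.40), SLY2 (CEI replicate 1 1.58, CEI replicate 3 1.67) and AT5G62330 (SHR 0 h replicate 1 2.43, CEI replicate 1 2.94). Against the SCR line alone the calls of SLY2 (1.74), AT1G09750 (−2.20), AUR1 (1.18), AUR2 (1.07) and WRKY53 (−0.99) ended, and so did those of the CML and WRKY families (medians −0.85 and −0.99, adjusted p = 0.0648 and 0.0890). Against the SHR line alone those of AT5G62330 (2.19), AT1G62500 (−1.13), AT1G09750 (−1.47), AUR1 (1.10) and the auxin list (median −0.59, adjusted p = 0.238) ended. Planned settings ended further calls. The replicate block, which gives CEI replicate 3 no weight, ended AUR2 (1.44, adjusted p = 0.0522) and AT1G62500 (−1.51, adjusted p = 0.0913). AT1G62500 also ended with a pseudocount of 1 (adjusted p = 0.0526) or no filter (0.0525). AT1G09750 ended with no filter (adjusted p = 0.0542) or only the arrays of the contrast (0.0765).

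Against ground tissue after 12 h of Dex 889 probe sets were higher and 1233 lower in CEI cells that were so at 0 h too. The same 3 CEI arrays serve both comparisons, so shared calls are expected from them alone. XTH21 was higher by 4.12 ± 0.48 (SE, adjusted p = 4.16e-05), ATGSTF13 by 3.52, AT3G32030 by 3.35, AT5G04120 by 3.32, AT5G62330 by 3.28, AT3G50190 by 3.27 and BBM by 2.35. AT2G38870 (−6.17), AT2G19970 (−5.46), AT5G64120 (−5.10), GH3.3 (32.1-fold), AT3G10950 (−4.60) and AT1G14550 (−4.34, a peroxidase) were lower, as were STZ (−2.46), WRKY53 (−1.86), GI (−1.32) and AT1G09750 (−1.91). For GH3.3 the log2 difference was −6.79 against the SCR line alone and −3.22 against the SHR line alone. The gibberellin receptor GID1B was lower at −1.14 (adjusted p = 0.0218, 1 of 3 called and 2 adjusted over the list alone), and LBD16 at −1.29 (adjusted p = 0.0255). Both rest on the SCR line: GID1B had a signal of 83.4 ± 21.2 (SD, n = 3) in CEI cells, 95.8 ± 50.5 (n = 2) in the SHR line and 403 ± 16.6 in the SCR line, and LBD16 66.9 ± 44.9, 44.6 ± 5.65 and 523 ± 193.

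Other genes did not pass against the 12 h cells. SLY2 differed by 0.09 ± 0.46 (SE, adjusted p = 0.908), AT1G62500 by 0.16 (adjusted p = 0.852), AUR1 by 0.74 (adjusted p = 0.145) and AT1G05370 by −0.79 (adjusted p = 0.205). The auxin list was lower (median −1.09, adjusted p = 0.0405, and adjusted p = 0.492 with an estimated correlation; 2 called, and 2 adjusted over the list alone). This rests on the SCR line, with a median of −2.11 against it alone (adjusted p = 0.0172) and −0.08 against the SHR line alone (adjusted p = 0.577). The call ended without SCR 12 h replicate 2 (−0.80) or CEI replicate 2 (−1.19) or 3 (−0.65). Of the other lists, stress genes (2 of 2), cortex (1 of 2), BBM (1 of 2) and GI (1 of 1) passed, in the same numbers adjusted over the list alone. The WRKY (median −1.45, adjusted p = 0.0296), CML (−0.93, adjusted p = 0.0111) and plastid (−0.84, adjusted p = 6.15e-12) families were lower, and none held with an estimated correlation (adjusted p = 0.820). Against the SHR line alone the CML median was −0.46 (adjusted p = 0.114) and against the SCR line alone −1.38 (adjusted p = 0.0104). The WRKY call ended against either line (−1.17 and −1.70, adjusted p = 0.0627 and 0.0609) and without SHR 12 h replicate 1 (−1.53), and the plastid call held against both (−1.36 and −0.47).

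At 12 h the count was 2733, 1183 higher and 1550 lower, 1846 by more than 2-fold. It was 1662 without SCR 12 h replicate 2, 1733, 1801 and 1708 without CEI replicates 1, 2 and 3, 4134 with only the arrays of the contrast, and against 1 line alone (added after seeing the data) 5152 with the SCR line and 553 with the SHR line. Calls that ended without 1 array were AT5G62330 (SHR 12 h replicate 1 2.61, CEI replicate 1 3.05, CEI replicate 3 3.16) and AT1G09750 (SHR 12 h replicate 1 −1.42, SCR 12 h replicates −1.72 and −2.10, CEI replicate 1 −0.92). The others were WRKY53 (SHR 12 h replicate 1 −1.66, CEI replicate 2 −1.41) and GID1B (SHR 12 h replicate 1 −0.89, SCR 12 h replicates −1.12 and −1.16, CEI replicate 1 −1.10, CEI replicate 3 −1.01). LBD16 was the last (SHR 12 h replicates −1.23 and −1.34, SCR 12 h replicate 2 −1.10, CEI replicate 2 −1.24, CEI replicate 3 −0.89). Against the SHR line alone the calls of AT5G62330 (2.40), AT1G09750 (−1.89), WRKY53 (−2.02) and GID1B (−0.12) ended and LBD16 turned (0.33), and against the SCR line alone that of AT1G09750 ended (−1.92). The replicate block ended GID1B (−1.01, adjusted p = 0.0555) and LBD16 (−0.89, adjusted p = 0.0989). AT1G09750 also ended with no filter (adjusted p = 0.0510) or only the arrays of the contrast (0.0520).

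Whether the induced response is found in CEI cells was asked with controls from the other line, so that no array was shared. The 2 probe sets that rose in the SHR line at 6 or 12 h, AT1G05370 and 255422_at, had a median difference of 0.96 between CEI cells and the SCR line at 0 h, at the 96.9 percentile of 10000 random lists matched on expression, and AT1G05370 was called higher in CEI cells (1.61 ± 0.51 SE, adjusted p = 0.0480). For the SCR line the single probe set 259008_at differed by 0.68, at the 82.2 percentile, and was not called. Across genes, which are not independent replicates, the SHR-line change had r = −0.43, −0.07, 0.23 and 0.48 with the CEI difference at 1, 3, 6 and 12 h, and the SCR-line change r = −0.37, −0.23, −0.29 and −0.24.

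Lists of 2 and 1 probe sets carry little weight. The SHR median was 2.66 without SCR 0 h replicate 1, 1.93 without SCR 0 h replicate 2, 1.61 without either SHR 1 h array and 1.53 without SHR 0 h replicate 1, and the SCR value was −0.20 without SCR 6 h replicate 2, −0.31 without CEI replicate 2, 0.28 without SCR 12 h replicate 1, 1.82 without either SCR 1 h array and 2.25 without SCR 6 h replicate 1.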

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

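The tests of a labelling batch in the line difference were chosen after that result was seen, and the gene families were defined and their tests chosen after the annotation was seen; leaving out arrays in set tests was added after the results.

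The SHR and SCR lines differed in 3608 probe sets. Only the real grouping, 1 of 100 time-balanced groupings, gave as many (3204 in a fit with time as a term, against 1484 in the highest other). This argues against chance but cannot exclude it, since 100 groupings are few and arrays of a line may share runs. With the log2 3' to 5' signal ratio as a covariate, 95.7% of the called probe sets were still called. This does not decide on RNA quality, since that ratio is a mean of 3 control genes and hardly differed between the lines (1.99 and 1.90). The ubiquitin ratio ran higher in the SHR line (1.16 to 2.31 against 0.82 to 1.52) and the GAPDH ratio mostly lower (0.25 to 1.31 against 0.81 to 1.49). A labelling batch could have added to the line difference, because the spiked dap transcript had a lowest SHR-line signal of 112 against at most 8.40 elsewhere, and the spiked phe transcript 52.6 against at most 32.0. CEI arrays, which like the SCR line lack the spikes, lay nearer the SCR line in 25% of the called probe sets, but their place also depends on cell type, and probe sets called over 1 to 12 h showed at 0 h 48.9% of their size (36.7 to 63.8 without single arrays), where a batch asks for 75% or more and its absence for 50% or less, a bound inside that spread. The plastid genome, at a median of 0.74 at 0 h and 0.85 to 1.25 later, goes with a difference present before Dex; batch and line therefore cannot be told apart, and the biological difference between the lines stays open as untested.

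CEI cells set against ground tissue also gave more calls than any other grouping of the arrays, at 0 h (3543 in a fit of the 7 arrays, highest other grouping 406) and at 12 h (682, highest other 459). Only the real 1 of 35 groupings was as large in each, the smallest share that 35 groupings allow. Chance is thus argued against but not excluded. The 12 WRKY and CML probe sets had a median log2 difference of −1.26 in CEI cells at 0 h, with 10 of 12 below 0. Both families were called in this comparison on the same arrays, so these values are no separate support. A labelling batch that follows the spikes is argued against as the whole cause, since the median was −0.92 against the SCR line alone, which lacks the spikes as CEI cells do. Lacking the spikes does not show that both were labelled together, so another batch stays open. Without single arrays the median ran from −0.628 to −1.16. Its value nearest 0 fell just short of the bound that was asked for, 50% of −1.26 (−0.630). With 2 control arrays in place of 4 the calls of the WRKY and CML families ended (adjusted p = 0.0890 and 0.0648). The median was −1.26 with the mean 3' to 5' ratio as a covariate, which does not decide on RNA quality. That mean hides the ubiquitin ratio (log2), at 2.23 to 2.42 in CEI cells and 1.31 to 2.21 in the 0 h arrays. The control U12639 was high in CEI cells alone, but the sources used here do not say what it detects, so it does not show a batch. Plant line, medium, sort and any batch of the CEI arrays coincide with the cell type and cannot be told apart from it. The biological difference stays open as untested.

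The change of the SHR line at 12 h followed the CEI difference (r = 0.48 across probe sets), where that of the SCR line had r = −0.24. With the mean 3' to 5' ratio as a covariate r was 0.46, which does not decide on RNA quality. That mean hides the ubiquitin ratio (log2), at 2.23 to 2.42 in CEI cells and 1.31 to 1.52 in the SCR 0 h arrays. A single array could decide it in part: without SHR 0 h replicate 1 r was 0.26, close to 50% of its size (0.24). A return from an early response to the transfer could also contribute. For this the CEI difference was taken from later SCR-line arrays in place of the SCR 0 h arrays. There r was 0.50, and 0.41 with the 1 h change of the SCR line held constant. Without single arrays the latter ran from 0.15 to 0.51, and at least 55.6% of r was kept. The 0.15 is not to be set against 0.50, which is from all arrays. An effect of a single array and such a return cannot be told apart from a shift towards the CEI state, since no time course without Dex is among the samples.

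The control probe set U12639 had a lowest signal of 304 in CEI cells against at most 27.6 in the time course. At 1 h the change from 0 h was higher in the SHR line than in the SCR line, by the test of that difference, for gibberellin (median 0.85, adjusted p = 0.0258, and adjusted p = 0.406 with an estimated correlation) and auxin lists (1.47, adjusted p = 0.0115, and adjusted p = 0.435 with an estimated correlation). The same held at 1 h for expansins (EXPA, 0.81, adjusted p = 0.0296), mitochondrial nad genes (0.87, adjusted p = 0.000183), tetraspanins (TET, 0.72, adjusted p = 0.0262) and the plastid genome (0.56, adjusted p = 2.24e-06). At 3 h the difference was −0.64 for ATG genes (adjusted p = 0.000497) and 0.43 for the plastid genome (adjusted p = 0.00198). At 12 h it was −1.13 for ATG genes (adjusted p = 0.000265), −1.75 for CML genes (adjusted p = 0.00298), −1.20 for GSTU genes (adjusted p = 0.0132) and −0.77 for vacuolar sorting genes (VPS, adjusted p = 0.0270). None of the family calls held with an estimated correlation (adjusted p of 0.820 or more).

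The ATG and CML differences at 12 h kept their calls without any 1 of the 8 arrays, and the others did not. Without SHR 0 h replicate 2 the calls ended for the gibberellin (0.68) and auxin lists (0.86), TET (0.04) and the plastid genome (0.19) at 1 h, the plastid genome at 3 h (−0.01, a turn in the median), and GSTU (−1.05) and VPS (−0.91) at 12 h. Without SHR 0 h replicate 1 they ended for EXPA (0.78) and for ATG at 3 h (−0.43). Without SHR 1 h replicate 1 they ended for gibberellin (0.91), auxin (0.97) and TET (0.37), and without SHR 1 h replicate 2 for EXPA (0.71) and nad (0.75). Without SCR 0 h replicate 1 they ended for TET (0.56) and the plastid genome at 3 h (0.24), and without SCR 0 h replicate 2 for gibberellin (0.84), auxin (1.25), EXPA (0.75) and VPS (−0.69). Without SCR 1 h replicate 1 they ended for gibberellin (0.68), EXPA (0.92) and TET (0.73), and without SCR 1 h replicate 2 for auxin (1.05) and nad (0.27), while the plastid difference at 1 h turned (−0.06). Others ended without SHR 3 h replicate 1 (plastid genome, 0.28), SHR 3 h replicate 2 (ATG, −0.46), SCR 3 h replicate 1 (plastid genome, 0.07) and SHR 12 h replicate 1 (VPS, −0.61).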

How the results depend on the processing

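The alternatives with a single control line for CEI cells (counts, genes and sets), set tests with single arrays left out, without the 12 h arrays and with the 3' to 5' covariate were chosen after the data were seen.

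Counted per gene and setting, 58 calls of named genes were lost with single arrays left out and 26 with other settings, and 1 turned, LBD16 in CEI cells at 12 h against the SHR line alone (0.33). Set tests lost 118 calls and kept 238 under other settings, with 0 turned, and lost 105 and kept 307 with single arrays left out, with 2 turned. These were the plastid genome in the SHR line at 3 h without SHR 0 h replicate 2 (adjusted p 1.65e-08 to 0.543 over left-out arrays) and its difference between the lines at 1 h without SCR 1 h replicate 2 (6.46e-19 to 0.873). 1 call was gained, SLY2 in the SHR line at 6 h with a replicate block. Where counts and values moved, the cause was not tested. With only the arrays of the contrast the SHR 6 h count was 0, the SHR F-test 60, SCR 12 h 270, CEI cells at 12 h 4134 and the SHR response in CEI cells 1.95. A pseudocount of 1 gave 2 (SHR 12 h), −0.14 (correlation of the lines at 12 h) and 2.85 (SHR response), and a pseudocount of 40 gave 1 each (SHR F-test, SCR 1 h, SCR 6 h), −0.24 and 0.47. Without filter SCR 12 h was 2, the correlation −0.14 and the SCR response 0.31. Quantile normalization gave 1 (SCR 1 h) and 2 (SCR 6 h), and eBayes without trend 1 (SCR 1 h), 2 (SCR 12 h) and 0.31. CEI cells gave 1827 and 2123 at 0 h against the SCR or SHR line alone, and 5152 and 553 at 12 h; the line difference was 1443 without the 12 h arrays.

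The labels do not say that a replicate number marks a shared batch or day. Differences between replicates correlated across time points by a median of 0.39 in the SHR line, 0.24 in the SCR line and 0.02 between lines. Above 0.1 were 9 of 10 pairs of times in the SHR line (lowest 0.05) and 8 of 10 in the SCR line (lowest −0.22), against 6 of 25 between lines. Replicate number thus carried shared variation within a line, most clearly in the SHR line, and the main fit leaves it out. The replicate block gave 332, 1, 20 and 6 probe sets for the SHR line at 1, 3, 6 and 12 h, 1254 in its F-test (all 3 called without the block among them), 3, 4 and 4 for SCR 1, 6 and 12 h, 4 in its F-test, 91 for the difference between the lines, and 0.45 for the SCR response.

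Leaving out single arrays, where the lone array left is assumed to vary like the other groups, gave SHR 1 h 0 to 0, 3 h 0 to 1, 6 h 0 to 2, 12 h 0 to 1 and F-test 0 to 147; SCR 1 h 0 to 90, 3 h 0 to 0, 6 h 0 to 1960, 12 h 0 to 3 and F-test 0 to 526; difference between the lines 0 to 3, 0 to 1, 0 to 1321 and 0 to 1 at 1, 3, 6 and 12 h and 0 to 1214 in the F-test; mean line difference 2633 to 5380; CEI cells 1766 to 2829 at 0 h and 1662 to 2083 at 12 h; correlation of the lines −0.28 to −0.040; SHR response 0.83 to 2.66; SCR response −0.31 to 2.25, reversed without SCR 6 h replicate 2 (−0.20) and without CEI replicate 2 (−0.31). The SCR response had no value with only the arrays of the contrast, nor had the correlation of the lines there or without trend. Signals near the pseudocount of 10 limit fold changes of weak genes.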

Other observations

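The tests of gene families here were chosen after the annotation was seen, and leaving out arrays in them after the results, while the division and replication lists were fixed before the data were examined.

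UDP-glycosyltransferases (UGT, 36 probe sets), which attach sugars to small molecules, rose in both lines at 1, 3 and 6 h. The median log2 change in the SHR line was 0.42 at 1 h (adjusted p = 0.00196), 0.37 at 3 h and 0.16 at 6 h. In the SCR line it was 0.21 at 1 h (adjusted p = 0.00250), 0.18 at 3 h and 0.29 at 6 h. In CEI cells they were lower than in ground tissue at 12 h (median −0.60, adjusted p = 0.00606), with 10 called lower and 1 higher. The median was −0.53 against the SCR line alone and −0.32 against the SHR line alone (adjusted p = 0.0130 and 0.0471). The SHR-line calls ended without SHR 1 h replicate 1 (0.33 at 1 h), SHR 3 h replicate 1 (0.11 at 3 h), SHR 6 h replicate 1 (0.07 at 6 h) or SHR 0 h replicate 2 (0.30 at 3 h and 0.25 at 6 h). Those of the SCR line ended without SCR 1 h replicate 2 (0.14 at 1 h), SCR 3 h replicate 1 (0.06 at 3 h), SCR 0 h replicate 2 (0.25 at 3 h) or SCR 6 h replicate 1 (0.04 at 6 h). The 13 probe sets of 7 mitochondrial nad genes, 6 of them for nad1, rose at 1 h in the SHR line by a median of 1.03 (adjusted p = 0.000167) and had a median change of −0.08 in the SCR line; the call ended without SHR 1 h replicate 2 (0.70). With an estimated correlation no UGT or nad call held (adjusted p of 0.820 or more).

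The tested genes of the division list (2 of 24 members) and the replication list (2 of 19) had low values at 1 h in both lines. The log2 differences from 0 h were −1.11 for AUR1, −0.93 for AUR2, −0.79 for PRL and −1.01 for ICU2 in the SHR line, none past the threshold over all probe sets. By 12 h they stood above 0 h in the SHR line (0.92, 1.37, 0.99 and 0.55) and below it in the SCR line (−0.13, −0.24, −0.58 and −0.39), also without a call. IAA genes were lower in the SHR line over all times (median −0.67, adjusted p = 0.0178), and the call was lost with an estimated correlation (adjusted p = 0.820).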
